A study of Mus musculus with 16 samples.

How the data were processed

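Total RNA of mouse embryonic stem cells was prepared with a silica column kit, per the labels' protocols. Biotinylated cRNA was made with the Affymetrix one-cycle assay, from PCR-amplified cDNA of 10 pg RNA for the 8 amplified arrays and from 5 µg RNA for the 8 nonamplified arrays, per the labels. The amplification method is named V1V3 in the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, with a lowest value of 1. The software that summarised probes into probe sets, and how the arrays were scaled to each other, are not given in the sources used here. Median intensities were alike within each group and differed between groups, and the values were therefore used as deposited, with other scalings as alternatives.

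The table holds 45101 probe sets. Of these, 64 Affymetrix control probe sets were left out of the tests across probe sets and examined separately. Gene names came from the platform annotation supplied with the series, updated through gene identifiers of the mouse RefSeq table of assembly GRCm38.p6. A single gene symbol was found for 34945 probe sets, of which 34741 matched a RefSeq gene, several symbols for 932 and none here for 9160. No gene was named from a probe set with several symbols, which is why Gapdh is reported through its control probe sets. Coordinates and transcript lengths were not used here.

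Values were transformed as log2(intensity + 16), so fold changes understate the change of dim probe sets. Probe sets whose mean over the 16 arrays was at or under the 40th percentile, an intensity of about 33.7, were left out, which leaves 27022. Groups were taken from the sample titles. They were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Counts of at least 2-fold use an absolute log2 fold change of at least 1. Gene lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, with 1 probe set per gene, that of the highest mean over the 16 arrays, and adjustment over 17 lists. Per-array measures and control transcripts were compared by exact 2-sided permutation tests of the difference of means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

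The tests, the alternatives, the 17 lists and the rule for named genes were fixed before the data were examined, except where stated. The lists were pluripotency genes, germ layer markers, extraembryonic markers, fibroblast feeder markers, blood cell markers, germ cell genes, housekeeping genes, ribosomal proteins, respiratory chain subunits, proteasome subunits, cell cycle genes, histones, very long mRNAs, chromatin regulators, glycolysis genes, stress response genes and signalling pathway genes. Named genes were the 8 with the largest positive and the 8 with the largest negative log2 fold change among called genes without overlap between groups. From each list came the 2 members with the highest nonamplified mean and the 2 with the largest absolute log2 fold change. The 5 most variable and 5 most stable genes on amplified arrays in the top 25% of the nonamplified mean were added, with the 5 brightest that dropped out on at least 4 of 8 amplified arrays, and Pou5f1, Nanog, Sox2, Actb and Gapdh. Of the genes this rule selects, the text gives the values of a part.

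The comparison was tested on simulated data with the observed SD of each probe set in each group. With 200 of 27022 probe sets changed, 61% of 100 changes of 1 and 79% of 100 changes of 2 on the log2 scale were called, with 0 wrong directions. In that simulation 34 of 26822 unchanged probe sets were called, which was 19.5% of the calls and above the nominal 5%. With 50% of the probe sets carrying their fitted difference, 3.69% of 8003 calls were unchanged probe sets. With weights per group the 2 shares were 43.9% and 5.32%. The camera step called the 1 list that was moved and 0 of 16 others. Its noise was drawn separately for each probe set and no other gene was moved, so it does not test the preset correlation. The correlation estimated from the data was 0.11 for ribosomal proteins and 0.071 for the respiratory chain.

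The alternatives were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, scaling on the brighter 50% of the probe sets, no filter, a 60th percentile filter, leaving out probe sets of type _x_at and _s_at, weights per group, a robust intensity trend, the replicate number as a block, tests against a minimum difference, an estimated correlation or the mean over the probe sets of a gene for the lists, other dropout percentiles, other level bins, the middle probe set of control transcripts, and leaving out each array in turn. Scaling on the hybridization controls and choosing the probe set of a gene by its nonamplified mean were added after the data were examined. No scan date or slide was used, so no technical batch was tested.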

Results

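Gene expression was measured on 16 arrays from a single preparation of total RNA of mouse embryonic stem cells of the line E14tg2a, a feeder-independent line derived from strain 129 embryos. For the amplified group (n = 8), RNA was diluted to 10 pg, about the amount in a single cell, and its cDNA was amplified by PCR in a separate reaction for each array. For the nonamplified group (n = 8), undiluted RNA (5 µg) was labelled directly. All arrays therefore carried the same RNA, and the comparison asks how far amplification from a single-cell amount changes measured expression. The replicates are technical, so no p-value here measures the spread between biological samples. Those of limma fits and permutation tests measure the spread between technical replicates. Those of camera set the genes of a list against the other genes. Median intensity was 35.0 ± 1.07 (SD, n = 8) on amplified arrays and 51.7 ± 1.44 (SD, n = 8) on nonamplified arrays. The lowest listed value, an intensity of 1, was reached by 7.53% ± 0.60 (SD, n = 8) of probe sets on amplified arrays and 2.55% ± 0.38 (SD, n = 8) on nonamplified arrays. The number of arrays limits the precision of each value.

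Genes of the stem cell state changed in both directions after amplification. Among 34 tested pluripotency genes, 9 were higher, 11 were lower and 14 did not pass the test. Pou5f1, the transcription factor Oct4, measured 4159 ± 213 (SD, n = 8) without amplification and 3155 ± 464 (SD, n = 8) after it, a log2 fold change of −0.41 (SE 0.089, limma adjusted p = 0.000845). Sox2, the DNA-binding partner of Oct4, went from 4050 ± 138 to 5047 ± 327 (SD, n = 8 each; log2 fold change 0.31, SE 0.066). Nanog, a homeodomain factor of the same network, fell from 1776 ± 61.0 to 276 ± 79.5 (SD, n = 8 each; log2 fold change −2.66, SE 0.14, limma adjusted p = 4.41e-11). Lin28a, an RNA-binding protein that blocks let-7 maturation, fell from 1978 to 96.6, a log2 fold change of −4.18 (SE 0.13). Dppa5a and Tdgf1, the brightest members of the list without amplification, differed by 0.31 and 0.59 on the log2 scale. Sox2, Dppa5a and Tdgf1 were lower instead under quantile normalization and did not pass when scaled on the hybridization controls. The difference of Pou5f1 was 0.0010 with each array centred on its median and did not pass when scaled on the brighter 50% of the probe sets (−0.19, limma adjusted p = 0.0600). As a list the pluripotency genes were not shifted (camera adjusted p = 0.774), with a median log2 fold change of 0.0017, a mean of −0.21 and a test direction of lower. Under quantile normalization the list was called lower (mean shift −0.81, adjusted p = 2.41e-05).

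With 1 probe set per gene, that of the highest mean over the 16 arrays, the largest increases were in genes near background without amplification and bright on all 8 amplified arrays. Other probe sets of some genes changed by more than several of the genes named here, such as Tmsb10 (log2 fold change 8.02) and Ddx3x (−7.02), chosen after their values were seen. Cxcr6, a chemokine receptor, measured 14.5 ± 6.06 without amplification and 9094 ± 559 after it (SD, n = 8 each; log2 fold change 8.24, SE 0.11). Hand1, a transcription factor of trophoblast and heart, went from 38.1 ± 11.3 to 13499.7 ± 446 (SD, n = 8 each; log2 fold change 7.99), while its other tested probe set had a log2 fold change of −0.29. Tprkb, a subunit of a tRNA-modifying complex, had a log2 fold change of 7.39, and another of its 3 probe sets −3.15. Cmbl, Ncam2, Dgki, Npat and Parp3 had log2 fold changes of 7.70, 7.50, 7.17, 7.13 and 6.93. The other tested probe set of Npat had 1.19 and that of Parp3 had 0.18. Among the genes with the largest decreases by the same choice of probe set, Nop58, a core protein of box C/D small nucleolar particles, fell from 2329.7 ± 131 to 23.5 ± 10.3 (SD, n = 8 each; log2 fold change −5.94). Prmt1, an arginine methyltransferase, fell from 3259 to 42.6 (log2 fold change −5.82, SE 0.094). Ftsj3, a ribosomal RNA methyltransferase, fell from 885 to 1.32, close to the floor of the table. Pdia3, Rsl24d1, Zmynd10, Snrpd3 and Rian had log2 fold changes of −5.69, −5.02, −4.93, −4.84 and −4.57. One of the other probe sets of Rian had a log2 fold change of 0.40, and one of those of Snrpd3 had −0.17.

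Of 27022 tested probe sets, 15543 (57.5%) differed between the groups at an adjusted p under 0.05 (limma, 2-sided), 6677 higher and 8866 lower in the amplified group. The difference was at least 2-fold for 9338 probe sets, 3373 higher and 5965 lower. The amplified and nonamplified values did not overlap for 9068 probe sets (33.6%), where chance gives 0.0155%. With 1 probe set for each of 13660 genes, that of the highest mean over the 16 arrays, 3743 genes were higher and 3387 lower. This choice uses the amplified values, and with the probe set of the highest nonamplified mean, an alternative added after the data were examined, the balance turned to 3253 higher and 4079 lower. The balance of directions followed the scaling of the arrays. Of the calls, 43.0% were higher as deposited, 50.9% under quantile normalization, 54.1% when scaled on the brighter 50% of the probe sets and 63.2% with each array centred on its median. The corresponding median log2 differences over all tested probe sets were −0.17, −0.026, 0.045 and 0.24. Scaling on the hybridization control probe sets, chosen after the data were examined, gave 22.1% higher and a median of −0.61. Against log2 differences of 0.5 and 1 in place of 0, 9234 and 5110 probe sets passed. Counts fell to 10148 with the 60th percentile filter, which tests fewer probe sets, and 2-fold calls to 6185 with a pseudocount of 64.

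Subunits of the respiratory chain and cytosolic ribosomal proteins were the lists called as shifted, both towards higher values in the amplified group. Of 72 tested respiratory chain subunits encoded in the nucleus, 48 were higher and 8 lower, with a median log2 fold change of 0.96 (camera adjusted p = 8.53e-09). The call did not hold with an estimated correlation (adjusted p = 0.0867). Ndufb2 and Ndufa6 of complex I rose from 697 to 7621 and from 899 to 7305 (log2 fold changes 3.41 and 2.98). Uqcrb of complex III rose from 4651 to 13652 (log2 fold change 1.55), whereas Atp5b, the catalytic subunit of ATP synthase, fell from 5316 to 2406 (log2 fold change −1.17). Of 46 ribosomal proteins, 31 were higher and 6 lower, with a median log2 fold change of 0.43 (camera adjusted p = 8.65e-05). With an estimated correlation the adjusted p = 0.272, so this call did not hold either. Rps29 rose from 9795 to 14421 and Rpl13a from 9659 to 11485. Under quantile normalization Rpl13a was lower and Rps29 did not pass (log2 fold change 0.0065), and scaled on the hybridization controls neither of them passed. Rps27 went from 83.9 to 7834, a log2 fold change of 6.30, and Rpl37 from 967 to 6262. Under quantile normalization the ribosomal list was called in the opposite direction (mean shift −0.17, adjusted p = 0.0236) and the respiratory chain list was not called (adjusted p = 0.108). Without probe sets of type _x_at and _s_at the ribosomal list was not called (adjusted p = 0.167), nor was it when scaled on the hybridization controls (adjusted p = 0.334). That scaling moves all probe sets of an array alike, so the mean shift of 0.45 cannot change under it. Over the alternatives run, the adjusted p ranged from 3.1e-11 to 0.108 for the respiratory chain and from 8e-07 to 0.334 for ribosomal proteins. Among 100 splits of the 16 arrays, 25 gave at least 2 called lists. None of the 35 splits with 4 amplified arrays in each group did, but there the real contrast cancels and adds to the spread within groups.

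None of the other 15 lists was called by camera with the values as deposited. Under quantile normalization the signalling pathway, proteasome, cell cycle, housekeeping and glycolysis lists were called lower (adjusted p = 0.00882, 0.000453, 0.0236, 0.0451 and 0.00412). Among 31 genes of the LIF, BMP, Nodal, FGF and Wnt pathways, 4 were higher and 11 lower, with a median log2 fold change of −0.48 (adjusted p = 0.282). Dusp6, a phosphatase of ERK, fell from 451 to 26.8, whereas Id1, a target of BMP signalling, rose from 683 to 5858. With the mean over the probe sets of each gene in place of 1 probe set, this list was called lower too (adjusted p = 0.00498, with a range of 0.00498 to 0.365 over the alternatives). It was not called with an estimated correlation and 1 probe set per gene (camera adjusted p = 0.272). Of 32 cell cycle genes 17 were higher and 8 lower, with a median log2 fold change of 0.47 (adjusted p = 0.367). Kif11, a mitotic kinesin, fell from 753 to 104 and Plk1, a mitotic kinase, rose from 944 to 3894. Plk1 did not pass under quantile normalization (log2 fold change 0.91, limma adjusted p = 0.0604). Of 38 proteasome subunits 16 were higher and 13 lower (adjusted p = 0.797), and their median of 0.23 and mean of −0.14 differed in sign. Psmb7 fell from 2668 to 449.7, and Psmd7 had probe sets with log2 fold changes from −2.83 to 3.83. Of 15 housekeeping reference genes 8 were higher and 2 lower (adjusted p = 0.539). Actb, cytoplasmic actin, fell from 3199 ± 314 to 1622 ± 312 (SD, n = 8 each, log2 fold change −0.99). Its other tested probe set had a log2 fold change of −4.23. Eef1a1, a translation elongation factor, had a log2 fold change of −0.045 (adjusted p = 0.550) under the values as deposited. It was called higher with each array centred on its median (0.36) or scaled on the brighter 50% of the probe sets (0.17), and lower under quantile normalization (−0.59) or scaled on the hybridization controls (−0.48). Of 18 glycolysis genes 6 were higher and 3 lower (adjusted p = 0.683). Ldha, lactate dehydrogenase A, had a log2 fold change of 0.17 that turned to −0.51 under quantile normalization. It did not pass with weights per group (limma adjusted p = 0.211) or with the replicate number as a block (limma adjusted p = 0.0949).

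Chromatin and DNA methylation regulators held 13 higher and 8 lower members of 32 (adjusted p = 0.774), with a median of 0.16 and a mean of −0.023. Smarcc1, a subunit of the BAF complex, fell, with a log2 fold change of −3.18. Smarca4, the ATPase of that complex, rose from 773 to 3816 at its brightest probe set, while its other probe set had a log2 fold change of −1.63. Of 22 stress response genes 9 were higher and 5 lower (adjusted p = 0.591), Junb rising from 234 to 1650.0 and Hmox1, heme oxygenase, falling from 369 to 55.3. Very long mRNAs had 8 higher and 8 lower members of 34 (adjusted p = 0.983), with a median of 0.00031 and a mean of −0.12. Of 8 tested genes in the histone list 3 were higher and 0 lower (adjusted p = 0.282). H2az1 and H2az2, which are replication-independent variants and not replication-dependent histones, were among these 3, with log2 fold changes of 1.80 and 2.44, and the other probe set of H2az2 had −0.88. Markers of other cell types showed no called shift. Extraembryonic markers had 7 higher and 3 lower of 17 (adjusted p = 0.423), and fibroblast feeder markers 7 higher and 4 lower of 19 (adjusted p = 0.797), with a median of −0.093 and a mean of 0.10. Blood cell markers had 6 higher and 2 lower of 12 (adjusted p = 0.516), germ layer markers 6 higher and 3 lower of 22 (adjusted p = 0.983; median −0.010, mean 0.016) and germ cell genes 2 higher and 6 lower of 13 (adjusted p = 0.450). S100a6, a calcium-binding protein of fibroblasts, rose from 324 to 1370.4, and Fcer1g, an immune receptor subunit, from 9.56 to 315. Adjusted over the list alone, the counts were the same for 12 lists. They were 48 higher and 10 lower for the respiratory chain, 17 and 13 for the proteasome, 8 and 3 for housekeeping genes, 7 and 8 for very long mRNAs, and 13 and 9 for chromatin regulators.

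**Figure D1:**
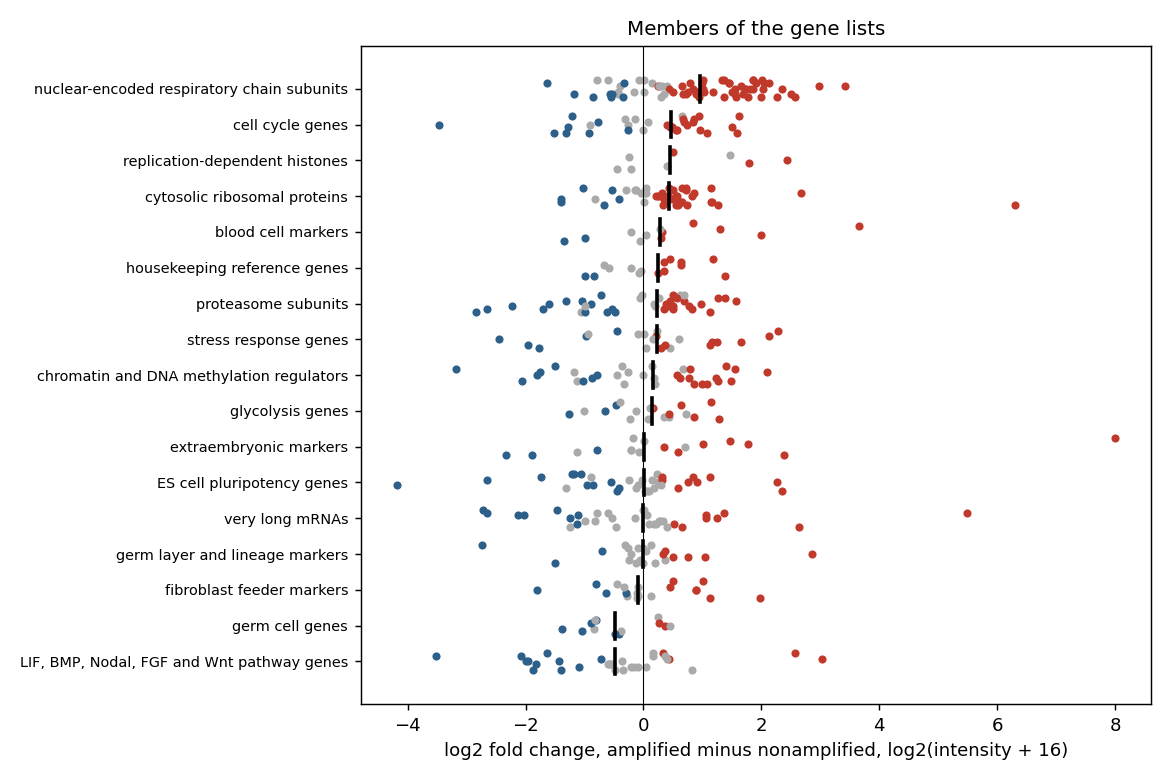
Each point is a gene of a list, placed by its log2 fold change between the amplified and nonamplified groups (8 arrays each) on the log2(intensity + 16) scale. Red points were called higher, blue points lower and grey points were not called, and the black bar is the list median, which was 0.96 for the respiratory chain and −0.48 for the signalling pathway genes.

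Probe sets of the same gene often disagreed. Among 5605 genes with at least 2 tested probe sets, the intraclass correlation of their log2 fold changes was 0.18 (95% bootstrap interval 0.16 to 0.21, 1000 resamplings of genes). In 6.99% of these genes one probe set was at least 2-fold higher and another at least 2-fold lower. The median range within a gene was 1.35 on the log2 scale. Ctnnb1, beta-catenin, had a log2 fold change of 0.43 at its brightest probe set (−0.37 under quantile normalization) and −6.02 at another, and Hsp90aa1 had values from −4.09 to 1.11.

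Amplified arrays differed more from one another than nonamplified arrays did. Rpl38, Tpt1, Hsp90aa1, Cox5b and Rps29 were the most stable well-expressed genes, with SDs over the 8 amplified arrays of 0.018 to 0.033 on the log2 scale. Gtf2h4, Epc2, Fam122b, Mpv17 and Atad2b were the most variable, with SDs of 3.13 to 3.44. These genes were picked for their SD, and the stable ones were the brighter, with nonamplified means of 2843 to 9795 against 374 to 609. Gtf2h4, a subunit of the transcription factor TFIIH, measured 609 ± 46.6 without amplification and 2654 ± 2254 with it (SD, n = 8 each). The median absolute log2 distance of an array from the mean of the other arrays of its group was 0.39 ± 0.025 (SD, n = 8) for amplified and 0.093 ± 0.0088 (SD, n = 8) for nonamplified arrays. This difference had an exact 2-sided permutation p = 0.000155, the smallest that 12870 regroupings can give, and the Benjamini-Hochberg value over 5 per-array measures was the same. Pearson r across probe sets averaged 0.81 over 28 pairs of amplified arrays, 0.98 over 28 nonamplified pairs and 0.71 across groups. Probe sets are not independent replicates, so these coefficients only describe agreement.

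Correlation of each amplified array with the nonamplified mean was 0.717 ± 0.013 (SD, n = 8), against 0.988 ± 0.0023 (SD, n = 8) for a nonamplified array and the mean of the others (exact permutation p = 0.000155). Spearman rho was 0.579 ± 0.019 and 0.974 ± 0.0053 (SD, n = 8 each; exact permutation p = 0.000155). On the linear scale r was 0.821 and 0.999. The 2 group means correlated with r = 0.785 and rho = 0.691 over 45037 probe sets.

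**Figure D2:**
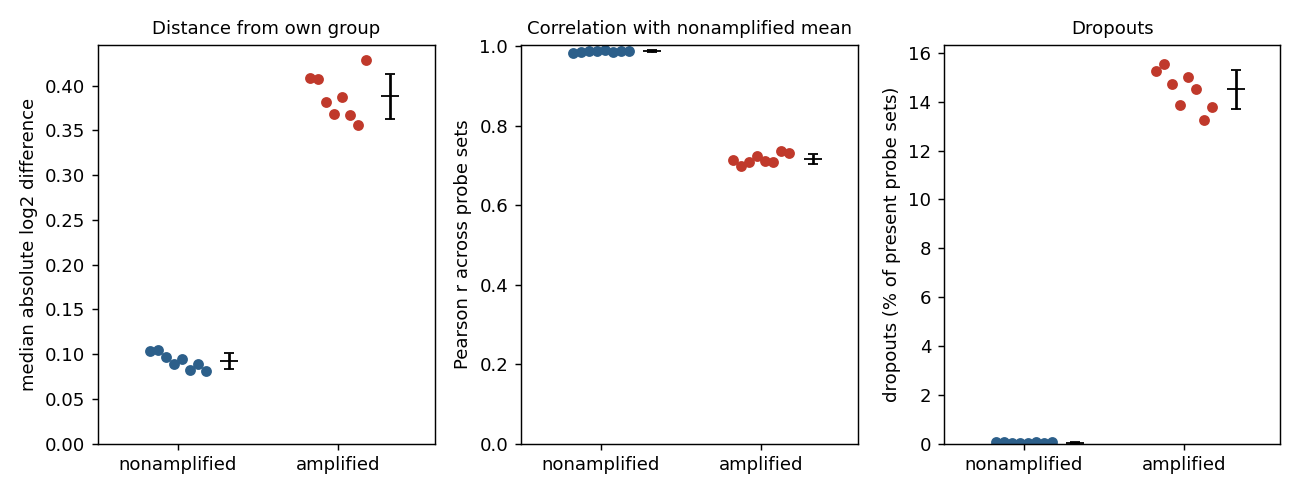
Each point is an array, grouped as nonamplified (blue) or amplified (red), and the black mark is the group mean ± SD of 8 arrays. From left to right the axes give the median absolute log2 distance from the own group, Pearson r with the nonamplified mean and the percent of present probe sets that dropped out; no amplified array overlapped a nonamplified one.

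With 1 probe set per gene, that of the highest mean over the 16 arrays, Insig1, a sterol sensor, was the brightest to drop out on at least 4 amplified arrays, followed by Ftsj3, Zmynd10, Kif11 and Sash1. A dropout is a probe set in the upper 50% of the nonamplified mean that lies under the 25th percentile of an array. Each nonamplified array was left out of the mean it was set against, but the reference is the nonamplified group and the measure counts departures from it. Insig1 measured 1003 ± 93.0 without amplification and 229 ± 406 after it (SD, n = 8 each), with dropouts on 4 arrays, and Ftsj3 dropped out on all 8. Dropouts made up 14.5% ± 0.80 (SD, n = 8) of present probe sets on amplified arrays and 0.0466% ± 0.023 (SD, n = 8) on nonamplified arrays (exact permutation p = 0.000155). Of 22518 present probe sets, 13995 (62.2%) dropped out on no amplified array, 3146 (14.0%) on at least 4 and 193 (0.857%) on all 8. In 5 equal groups of present probe sets from the lowest to the highest level, dropouts averaged 19.3%, 19.6%, 18.3%, 12.2% and 3.14%. A probe set of random rank would lie under the 25th percentile in 25% of cases. The lowest groups had median nonamplified intensities of 60.5 and 87.2, where the median of nonamplified arrays was 51.7. No detection call was used, so a dropout there is not shown to be a lost transcript.

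The spread between amplified arrays was largest at upper-middle levels on the log2(intensity + 16) scale, which compresses the spread of dim probe sets. No other pseudocount or binning was run for the SD by level. In 10 bins by mean level over the 16 arrays, the mean SD over amplified arrays rose from 0.37 in the lowest bin to 1.13 in bin 9 and was 0.71 in bin 10. Over nonamplified arrays it went from 0.34 in the lowest bin to 0.074 in bin 10. In bin 9, 41.9% of probe sets differed at least 2-fold between a pair of amplified arrays, against 0.166% between a pair of nonamplified arrays. The mean log2 difference between groups was −0.11 in the lowest bin, −0.43 in bin 8 and 0.41 in bin 10. The direction of this trend depended on how levels were binned, since the highest bin minus the lowest was 0.52 with bins by all arrays and −0.67 with bins by odd-numbered nonamplified arrays and differences against even-numbered ones. It was −0.45 under quantile normalization.

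**Figure D3:**
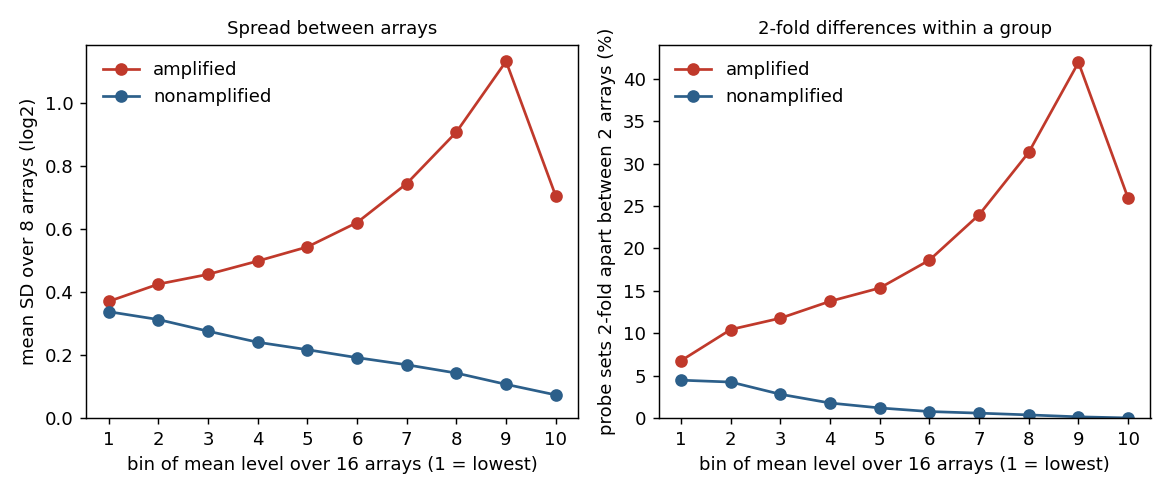
Probe sets are binned by mean level over the 16 arrays, with bin 1 the lowest. The left axis gives the mean SD over the 8 arrays of a group on the log2 scale and the right axis the percent of probe sets at least 2-fold apart between 2 arrays of a group; the amplified curves (red) peak at 1.13 and 41.9% in bin 9.

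Control transcripts with probe sets at both ends differed in the balance of signal along their length. Gapdh, the glycolytic enzyme, kept 112% of its nonamplified intensity at the 3′ probe set and 37.6% at the 5′ probe set. The 3′ minus 5′ difference of Gapdh was larger in the amplified group by 1.63 on the log2 scale. For the Bacillus subtilis control transcripts lys, phe and dap it was larger by 2.15, 3.82 and 5.21. Each of these transcripts has a second set of control probe sets, which was not used for these differences. In that set the log2 difference between groups was −0.44 at the 3′ and −3.17 at the 5′ probe set of lys. It was −0.83 and −2.01 for phe, and −1.15 and −4.65 for dap, so the sizes depended on the probe sets. The sources used here do not say whether or at which step these Bacillus controls were added. On amplified arrays lys kept 44.1% of its nonamplified intensity at the 3′ probe set and 10.2% at the 5′ probe set. In the second set these shares were 73.6% and 11.4%. A control added after amplification would not lose its 5′ end more than its 3′ end, so for lys these values argue against that. The 5′ probe sets of phe and dap used for the differences were too near the floor to add to this. In the second set phe kept 57.4% at the 3′ probe set and 23.0% at the 5′ one, which measured 76.2 to 167 on amplified arrays. For phe these values argue against addition after amplification too. Those of dap went the same way (46.1% and 2.98%), but its 5′ probe set was dim there (34.2 to 54.9). Whether the controls were diluted stays unknown. The differences of Gapdh, lys, phe and dap each had an exact permutation p = 0.000155 (n = 8 per group, Benjamini-Hochberg adjusted 0.000311 over 8 transcripts). The 3′ probe set of dap measured 46.9% of its nonamplified intensity. The 5′ probe set of dap used for its difference averaged 7.79 on amplified arrays and was at the floor of 1 on 4 of them. No share is therefore given for it, and the size of the difference is limited by the floor. For phe the 5′ probe set used averaged 10.2 on amplified arrays, so low that the difference depended on the pseudocount (5.27 with 1 and 2.46 with 64). Actb, Tfrc, Pcx and thr did not pass the adjusted threshold, with differences of 0.012, 0.23, −1.21 and −0.23 and adjusted exact p of 0.932, 0.281, 0.0505 and 0.737. The 3′ probe set of thr was at the floor of 1 on 5 of 8 amplified arrays, so its differences from the other probe sets are limited by the floor, and the 3′ minus 5′ value was −1.35 with a pseudocount of 1. Pcx passed without amplified replicate 1 (−1.51) or without amplified replicate 3 (−1.41), and Tfrc without amplified replicate 8 (0.33). Both passed with a pseudocount of 1 and neither with 64, where the difference of Tfrc turned to −0.22. The 5′ probe set of Tfrc averaged 23.4 on amplified arrays. The 3′ probe set of Pcx measured 74.9 ± 82.0 (SD, n = 8) on them. Its lowest value there was 1.41, so the differences of Pcx rest partly on values near the floor. Actb kept 15.1% at the 3′ end, 5.84% in the middle and 14.7% at the 5′ end. Set against the middle probe set in place of the 5′ one, all 8 transcripts passed, but the difference was negative for Tfrc (−1.37), Pcx (−1.18) and thr (−0.75, limited by the floor).

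**Figure D4:**
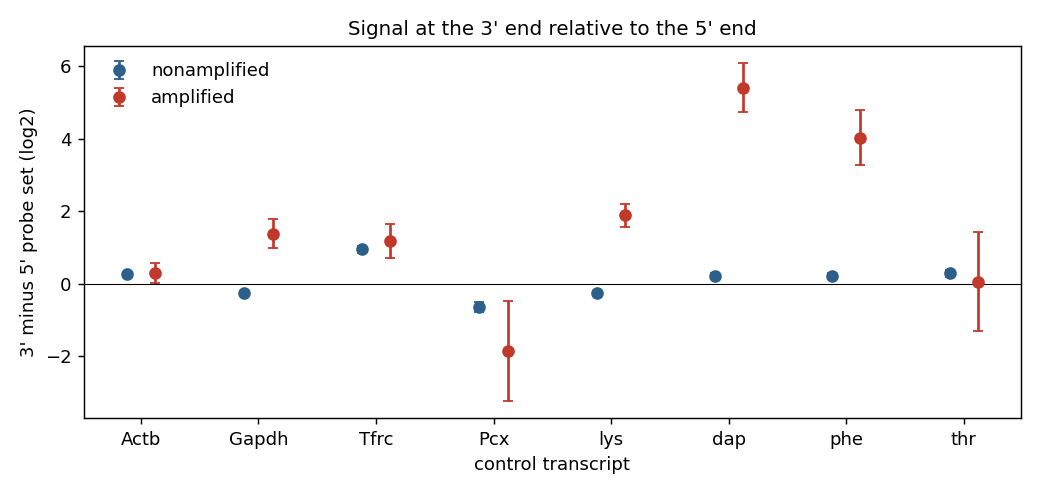
The vertical axis is the log2 intensity of the 3′ probe set minus that of the 5′ probe set for 8 control transcripts. Points and bars are the mean ± SD of 8 nonamplified (blue) or 8 amplified (red) arrays; the groups lie 5.21 apart for dap and 0.012 apart for Actb.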

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

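The tests of unequal loss within transcripts, of evenly mixed splits and of the dark probe sets that turn bright were chosen after the results were seen. Of 208 groups of 8 arrays examined for a value far from the others, 16 (7.69%) had one, where chance gives about 1 in 20, or 10.4. Each value below lay apart from the other 7 arrays of its group by more than Dixon's critical share of the range (0.526). In the amplified group these were Cxcr6 on replicate 7 (7900, median of the others 9364), Dgki on replicate 3 (5687), Lamb1 on replicate 3 (163, others 1155), Ascl2 on replicate 4 (341), Fn1 on replicate 5 (4266), Piwil2 on replicate 8 (184, others 33.2), Rpl13a on replicate 8 (13287), Psmb4 on replicate 5 (3348, others 8059), H2az1 on replicate 4 (9709), Trim28 on replicate 3 (6442) and Junb on replicate 2 (99.6, others 1750). In the nonamplified group they were S100a8 on replicate 2 (1.10, others 14.6), Piwil2 on replicate 8 (118), Uqcrb on replicate 2 (4911), the 3′ minus 5′ difference of Actb on replicate 5 (0.31) and that of phe on replicate 2 (0.037, others 0.22). Lamb1 was not called with all arrays and was called without amplified replicate 3 (log2 fold change 1.06, limma adjusted p = 8.13e-06).

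Among control probe sets outside the comparisons of the report, 18S ribosomal RNA was brighter after amplification at its 5′ and middle probe sets, by 4.81-fold and 8.10-fold (exact permutation p = 0.000155 each, n = 8 per group). Its 3′ probe set had an exact permutation p = 0.971 (n = 8 per group).

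The number of probe sets called cannot be put down to chance assignment of arrays. The real groups gave 15543 calls and 9338 calls of at least 2-fold, the highest of 99 other splits gave 10605 and 6406, and 1 of 100 splits, the real one, gave as many. For the 2 called lists the count over all splits does not exclude chance, since 25 of 100 gave at least as many and the highest other number was also 2, but it does not support chance either. The other splits with as many lists all carried part of the real contrast, being 13 of 51 with 5 amplified arrays in one group, 10 of 12 with 6 and 1 of 1 with 7. Of the 35 splits with 4 amplified arrays in each group, 0 gave as many. In these splits the real contrast cancels from the difference and adds to the spread within groups, so their count cannot decide. The count is of lists and does not test the shift of a single list.

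Probe sets of one gene differed widely in their response. Noise between arrays is argued against as the cause, since squared standard errors made up 8.58% of the variance within genes. Unequal loss of parts of a transcript stays open, since the intraclass correlation of 0.183 restates the disagreement, which cross-hybridization or wrong gene assignments would give too. In control transcripts the 3′ minus 5′ difference was larger for 4 of 8 and did not pass for the others, Actb among them. Of these 4, 3 are Bacillus controls whose step of addition is not stated, though the values of lys and phe argue against addition after amplification. Cross-hybridization and wrong assignments were not tested, and all arrays carried the same RNA, so no biological explanation was tested for this or for the other patterns.

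Respiratory chain and ribosomal protein genes had higher values in the amplified group as deposited. Abundance is argued against for the respiratory chain, whose median lay at percentile 100 of 10000 random lists matched on nonamplified level, and remains open for ribosomal proteins, at percentile 64.7. That short mRNAs in general are favoured is a hypothesis that stays open. After the lists were seen, 4 other gene families were picked as families of small proteins. Together they were shifted by 0.66 on the log2 scale (118 genes, camera adjusted p = 0.00026), a call lost with an estimated correlation (adjusted p = 0.0662). Their shift was 0.15 under quantile normalization (unadjusted p = 0.406 by camera of limma), where the respiratory chain list was not called either. Members were taken by gene name and their sizes were not checked, so not all need be small and the shift does not test length. At the other end of length, the very long mRNAs did not pass as a list (8 higher and 8 lower of 34, median 0.00031, camera adjusted p = 0.983), and mRNA lengths were not measured.

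A small set of probe sets was dark without amplification and bright after it. Of those under 50 on every nonamplified array, 39 exceeded 1000 on every amplified array, and 9 changed in the opposite way. Random sampling of rare mRNAs is argued against, since 41 of 47 such probe sets selected on odd-numbered amplified arrays (87.2%, exact binomial 95% interval 74.3 to 95.2) exceeded 1000 on all 4 even-numbered ones; an earlier comparison of SDs, 0.58 of that of other dark probe sets, did not decide and was limited by selection on the same arrays. Enrichment of the whole mRNA is argued against as the general rule for the 12 of 25 named genes with other tested probe sets. Of these 32 probe sets, 5 (15.6%, exact binomial 95% interval 5.28 to 32.8) were at least 2-fold higher. That interval treats the 32 probe sets as independent, although they belong to 12 genes. The share is pooled and does not decide for each gene. For Npat the only other tested probe set had a log2 fold change of 1.19, so enrichment stays open there. It also stays open for the other 27 of the 39 probe sets, 14 of them without a gene name. Hybridization of amplification products or primers to these probes was not tested, because probe sequences were not used here.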

How the results depend on the processing

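Scaling on the hybridization controls and choosing probe sets by the nonamplified mean were chosen after the results were seen. The larger distance within the amplified group, the lower correlation with the nonamplified mean and the dropouts kept their direction and stayed past the threshold under all alternatives run, with group differences of 0.19 to 0.37, −0.44 to −0.24 and 6.62 to 21.8 percentage points. Calls fell to 10148 with the 60th percentile filter and 9234 against a minimum difference of 0.5, and 2-fold calls to 6185 with a pseudocount of 64 and 5110 against a minimum of 1; fewer tested probe sets, a compressed scale and a stricter hypothesis are how these settings are built. Leaving out single arrays gave 14816 to 15760 calls and 9099 to 9478 2-fold calls. Replicate numbers do not pair the samples (correlations of same-numbered arrays −0.0078 to 0.018, and 3 of 8 correlated best with their own number). The replicate block gave 14856 calls, 9242 2-fold calls and 2 lists.

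The number of called lists was 2 as reported, 7 under quantile normalization, 1 without _x_at and _s_at probe sets, 1 when scaled on hybridization controls and 0 with an estimated correlation; it was 3 with the mean over the probe sets of a gene and 2 with the probe set of a gene chosen by its nonamplified mean. Under quantile normalization the camera direction of 5 lists turned to lower, with mean shifts of −0.39 for housekeeping genes, −0.17 for ribosomal proteins, −0.82 for the proteasome (already −0.13 as deposited), −0.53 for the cell cycle and −0.49 for glycolysis. Log2 fold changes that turned negative there were Dppa5a −0.24, Tdgf1 −0.19, Vim −0.35, Ifitm1 −0.48, Rpl13a −0.31, Psma3 −0.43, Mcm7 −0.45, Cbx1 −0.24, Ldha −0.51, Hspa8 −0.25, Hsp90aa1 −0.35, Ctnnb1 −0.37, Mycn −0.67 and Sox2 −0.52. Scaled on hybridization controls, the negative ones were Dppa5a −0.12, Csf1r −0.11, Ifitm1 −0.067, Rpl13a −0.19, Psma3 −0.013, Mcm7 −0.031, Ldha −0.26, Hspa8 −0.13, Hsp90aa1 −0.22 and Sox2 −0.12. Centring on the median turned Eef1a1 to 0.36, Pcna to 0.26, Dync1h1 to 0.40 and Pou5f1 to 0.0010, and scaling on the brighter 50% turned Eef1a1 to 0.17. Eef1a1 was called lower under quantile normalization (−0.59) and on hybridization controls (−0.48), Rps29 lost its call there (0.0065 and 0.12), and Plk1 under quantile normalization (0.91). The cause was not tested for any of these.

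Of the 3′ minus 5′ differences, those of Gapdh, lys, dap and phe stayed past the threshold throughout. With a pseudocount of 1 Tfrc (0.65) and Pcx (−1.77) passed; with 64 neither did, Tfrc being −0.22 and Pcx −0.74. Against the middle probe set all 8 passed, Actb at 1.79, Pcx at −1.18, thr at −0.75, limited by the floor, and Tfrc reversed at −1.37; the cause was not tested. Leaving out single arrays gave −1.51 to −0.94 for Pcx and 0.10 to 0.33 for Tfrc. The rise from the lowest to the highest level bin (0.52) turned to −0.67 with bins by odd-numbered nonamplified arrays and −0.45 under quantile normalization; the cause was not tested. Among named genes, leaving out single arrays reversed 0 log2 fold changes, ended 8 calls, all of Vim, and added 8. Signal near the floor limits dim probe sets.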

Other observations

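The gene families in this part were chosen after the comparisons of the report were seen. Mitochondrial ribosomal proteins, which translate the mRNAs of mitochondrial DNA, held 40 higher and 12 lower members of 73, with a median log2 fold change of 0.84 (camera adjusted p = 0.00172; adjusted p = 0.0697 with an estimated correlation). Mrpl34 rose from 584 ± 25.3 to 6480.2 ± 1038 and Mrpl57 from 781 ± 34.2 to 6936 ± 966 (SD, n = 8 each), named after their values were seen. Mitochondrial import subunits had 10 higher and 0 lower members of 22 (camera adjusted p = 0.0405, and 0.122 with an estimated correlation). Sm and LSm proteins had 9 higher and 3 lower of 14 (camera adjusted p = 0.0333, and 0.0662 with an estimated correlation). None of these 3 calls held with an estimated correlation or under quantile normalization (unadjusted p = 0.282, 0.965 and 0.405 by camera of limma), where the mean shift of the Sm and LSm proteins was −0.16.

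Kinesins, the microtubule motors, had 3 higher and 14 lower members of 30, with a median log2 fold change of −0.43 (camera adjusted p = 0.0405; adjusted p = 0.0662 with an estimated correlation). Under quantile normalization their mean shift was −0.66 (unadjusted p = 0.0235 by camera of limma), against −0.69 as deposited. RNA polymerase subunits picked as small (5 higher and 1 lower of 9), translation initiation factor (Eif) genes (18 and 10 of 46), hnRNP proteins (8 and 6 of 19), solute carriers (52 and 50 of 224), ubiquitin-specific proteases (9 and 12 of 41) and zinc finger proteins (44 and 56 of 239) were not called as deposited. The Eif genes were taken by name and include regulators such as Eif4ebp1 and Eif2ak1. Under quantile normalization the Eif genes, hnRNP proteins and ubiquitin-specific proteases had mean shifts of −0.43, −0.88 and −0.55 (unadjusted p = 0.00169, 0.000819 and 0.0296 by camera of limma). As deposited these shifts were 0.13, −0.18 and −0.47. Among repeat control probe sets, B1 fell from 1607 ± 88.4 to 286 ± 208, and the brighter of the B2 probe sets rose from 11174 ± 221 to 13645 ± 468 (SD, n = 8 each; exact permutation p = 0.000155 each).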
